A study of Homo sapiens with 4 samples.

How the data were processed

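Gene expression was measured in IMR-90 fibroblasts with 4 two-colour Agilent oligonucleotide arrays, 2 of cells transduced with wild-type ING4 and 2 of cells transduced with the N214D mutant. Each was hybridised against RNA of vector-infected cells, per the labels a single reference sample. Groups, replicate numbers and dyes were taken from the labels. The deposited scanner output holds one row per spot with intensity values, which per the file headers were extracted by Feature Extraction 10.1.1.1 from 1 scan of 1 slide with the array design annotated on build hg18. No coordinates are printed. The intensity values used here are the deposited median signal of the red and green pixels of a spot and the median of its local background. The design had named mean signals, which the deposited files do not hold. The deposited value table of the series is on a log10 scale. Set against the scanner output, its columns for 3 arrays equal the software's log10 ratio of red over green at every value within 0.6%, not turned for the dyes and not centred further. The column of the N214D replicate 1 array equals the software's error of that ratio instead, so the table was used for 3 arrays. The column medians were 0.00688 and 0.0115 for wild-type ING4 replicates 1 and 2, 0.0661 (the error) and 0.0166 for N214D replicates 1 and 2. Outlier flags and detection flags were also used as deposited, per the file headers.

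Arrays were read and tested with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and log ratios were normalized within each array by loess with control spots at weight 0. Each array's ratio was turned by the dyes in the labels to transduced over vector. Control spots and spots with an outlier flag were left out, spots of a probe were averaged, and 1 probe per gene was kept, the one with the highest mean log intensity. A probe had to be well above background in at least 1 channel on at least 2 of the 4 arrays. Probes were named through their accession, without versions, in a table of RefSeq genes of assembly GRCh38.p14: 23953 of 41000 probes matched, and the others keep the file's identifier. The tests ran on 23314 genes and unnamed accessions, 13470 with a symbol. Several probes of a gene were tested by themselves as an alternative, and no named gene had 2 probes past the threshold in opposite directions. Red signals were saturated at 546 to 662 spots per array and green signals at 0.

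Before the data were examined, the design fixed a limma fit over all 4 arrays with eBayes, the mean log ratio of each group against 0 and the difference of the group means, with Benjamini-Hochberg adjustment and a threshold of 0.05. It also fixed the fit with the replicate number as a block. The replicate number is the dye orientation in the labels, so this block carries the gene-specific dye effect together with any infection batch that follows the number. A dye effect of equal size on both arrays of a group cancels in the group mean and enters only the error. Where the sizes differ, the remainder stays in the mean. After turning, arrays of opposite orientation correlated at -0.52 (wild-type ING4) and -0.47 (N214D) across genes, and arrays of one orientation at 0.83 and 0.86. The deviations of replicate 1 from replicate 2 correlated between the constructs at r = 0.91. Values are therefore given with the block, next to the fit without it. Both fits were tested on simulated data made from the real genes, dye effects and spreads, with 200 changed genes. A gene's dye effect was of equal size on all 4 arrays there, with the spread left by the block. The vector sample had no deviation of its own. The assumptions of the block thus held by construction, so the outcome does not show which fit suits the real arrays. Without the block 0 of 100 genes changed 2-fold were found in each comparison against vector, and with it 100 of 100, with 27 and 21 calls among the unchanged ones of the 23314 genes for wild-type ING4 and N214D. The replicate block leaves 1 residual degree of freedom, and eBayes adds 8.97 from all genes.

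Gene lists, 41 in all, were fixed beforehand and tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. The estimate rests on 2 residual degrees of freedom, or 1 with the block, so not passing with it does not show that a list is unchanged. At the preset correlation the members are set against the other genes, so those p-values do not measure the spread between cultures. Members past the threshold in the fit with the block were counted over all genes tested and adjusted over the list alone. List p-values are of the fit without the block unless the block is named. Genes were named by a rule fixed beforehand. ING4 came first. In each comparison, among genes with a symbol, past the threshold and turned the same way on every array, the 12 largest rises and the 12 largest falls followed. Where fewer passed, the genes of smallest p turned the same way stood in until 6 were named, said not to have passed. For each list described, up to 4 members with the largest change among those past the threshold were taken, or 2 where none passed. The rule was applied to both fits. Its use on the blocked fit, and again with the streaked columns left out, was chosen after seeing the data.

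Alternatives were no background subtraction, the software's processed signals, a normexp offset of 16, median centring, Aquantile normalization between arrays, no or a stricter filter on dim probes, every probe tested, trended and robust eBayes, the replicate block, the value table, and each array left out in turn. Added after seeing the data were the block together with these choices, arrays scaled to one spread, the dyes of replicate 2 read as not exchanged, calls that need every array on one side, and array columns 73 to 81 left out. To show what a shared vector sample gives, unchanged groups were simulated against 1 vector sample, 100 times. Every sample, the vector included, had the residual spread of the fit with the block. That spread leaves out the replicate difference, and a vector culture may vary more.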

Results

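IMR-90 is a line of diploid fibroblasts from human lung. Cells at a population doubling level below 30 were infected with retrovirus that carried wild-type ING4, the N214D mutant of ING4 or an empty vector. ING4 is a PHD-finger protein of the HBO1 histone acetyltransferase complex. RNA of each transduced culture was hybridised together with RNA of vector-infected cells to one of 4 two-colour Agilent arrays on 1 slide, 2 arrays for wild-type ING4 and 2 for N214D. On the replicate 1 arrays the transduced cells carried Cy5 and the vector cells Cy3, and on the replicate 2 arrays the dyes were exchanged. Each array held 43376 spots that are not controls. Between 70.0% and 71.9% of them were well above background in the channel of the transduced cells, and between 69.4% and 73.3% in the channel of the vector cells. The number of arrays limits the precision. The labels do not settle whether the 2 arrays of a group came from separate infections, so the spread between them may be technical. Log2 ratios below are transduced over vector, the mean of 2 arrays ± SE (n = 2) of the fit with the replicate block. The block takes up the mean difference between replicates 1 and 2, be it dyes or batch. The SE and p-values therefore leave out most of the spread between the 2 arrays of a group. They rest on how far that difference varied between the constructs, with 1 residual degree of freedom moderated over all genes. A gene can pass with its arrays on both sides of 0: of 2960 calls for N214D, 1924 had both arrays on one side.

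The transcript of ING4 did not pass the test in either group. Its single probe, for NM_016162, gave log2 ratios of -0.21 and 0.11 on the arrays labelled wild-type ING4 and of -0.16 and 0.01 on those labelled N214D. The means were -0.05 ± 0.06 (limma adjusted p = 0.700) and -0.07 ± 0.06 (adjusted p = 0.449). N214D and wild-type ING4 differed by -0.03 ± 0.08 (adjusted p = 0.948). Both groups thus lay within the spread of their arrays. The sequence of the probe is not given in the sources used here. Whether it lies in the transduced coding sequence is therefore not known, the transcript checks no label, and the groups are named as labelled throughout.

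The comparison with vector asks which transcripts differ once wild-type ING4 is introduced. In the fit with the replicate block, the cells labelled wild-type ING4 had more RNA of POMC, MAL2, NNMT, SUCNR1 and FGG and less RNA of CLTRN, and 26 of 39 G2/M and mitosis genes rose and 8 of 34 interferon-stimulated genes fell. As lists these shifted in camera with a preset correlation but did not pass with an estimated one. With the estimated correlation, camera adjusted p was 0.220 and 0.295 in the fit without the block and 0.633 for each list with it. The largest rise was in POMC, the precursor of ACTH and beta-endorphin, at 2.47 ± 0.06 (5.54-fold, adjusted p = 2.81e-08), with 2.69 and 2.25 on the single arrays. MAL2, a protein of membrane transport, rose by 2.11 ± 0.06, NNMT, which methylates nicotinamide, by 1.89 ± 0.06, and FGG, the gamma chain of fibrinogen, by 1.81 ± 0.06. SUCNR1, a receptor for succinate, rose by 1.88 ± 0.08. The copper carrier ceruloplasmin, CP, rose by 1.16 ± 0.06, lipoprotein lipase, LPL, by 1.08 ± 0.06 and the matrix protein SVEP1 by 1.04 ± 0.06. TC2N rose by 1.02 ± 0.06, the complement protease C1R by 1.01 ± 0.07, the extracellular sulfatase SULF2 by 0.91 ± 0.06 and carbonic anhydrase CA12 by 0.90 ± 0.06. Each of these 12 lay above 0 on both arrays. SUCNR1 and SVEP1 were measured in array columns 73 to 81, which held a streak on the N214D replicate 2 array but gave these values on the wild-type arrays.

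Falls were smaller. CLTRN, which encodes collectrin, fell most, at -1.17 ± 0.06 (adjusted p = 5.67e-06), with -1.12 and -1.22 on the single arrays. SERPIND1, which encodes heparin cofactor II, stood at -0.89 ± 0.06, AATK at -0.88 ± 0.06 and NGEF at -0.88 ± 0.06. Both AATK and NGEF were also measured in array columns 73 to 81, and with these columns left out a different probe of AATK gave 0.03. APLN, which encodes the peptide apelin, stood at -0.85 ± 0.06, CAVIN3, a protein of caveolae, at -0.82 ± 0.06, and KCNMA1, a potassium channel, at -0.79 ± 0.06. The interstitial collagenase MMP1 was at -0.77 ± 0.06, ANXA10 at -0.74 ± 0.06, the endothelin receptor EDNRB at -0.74 ± 0.06, SLFN11 at -0.74 ± 0.06 and TOX2 at -0.73 ± 0.06. All 12 passed in the fit with the block and lay below 0 on both arrays. In all, 888 of 23314 genes were higher and 923 lower in limma with the replicate block. The fit without it called 0, with 478 genes at an unadjusted p under 0.05. The smallest p there belonged to NNMT, MAL2, FGG, POMC, SVEP1 and LPL among the genes above 0, with adjusted p from 0.334 to 1.00. Below 0 it belonged to CLTRN, SERPIND1, TOX2, HS3ST1 (-0.64), TNXB (-0.65) and TXK (-0.59), and none passed.

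**Figure D1:**
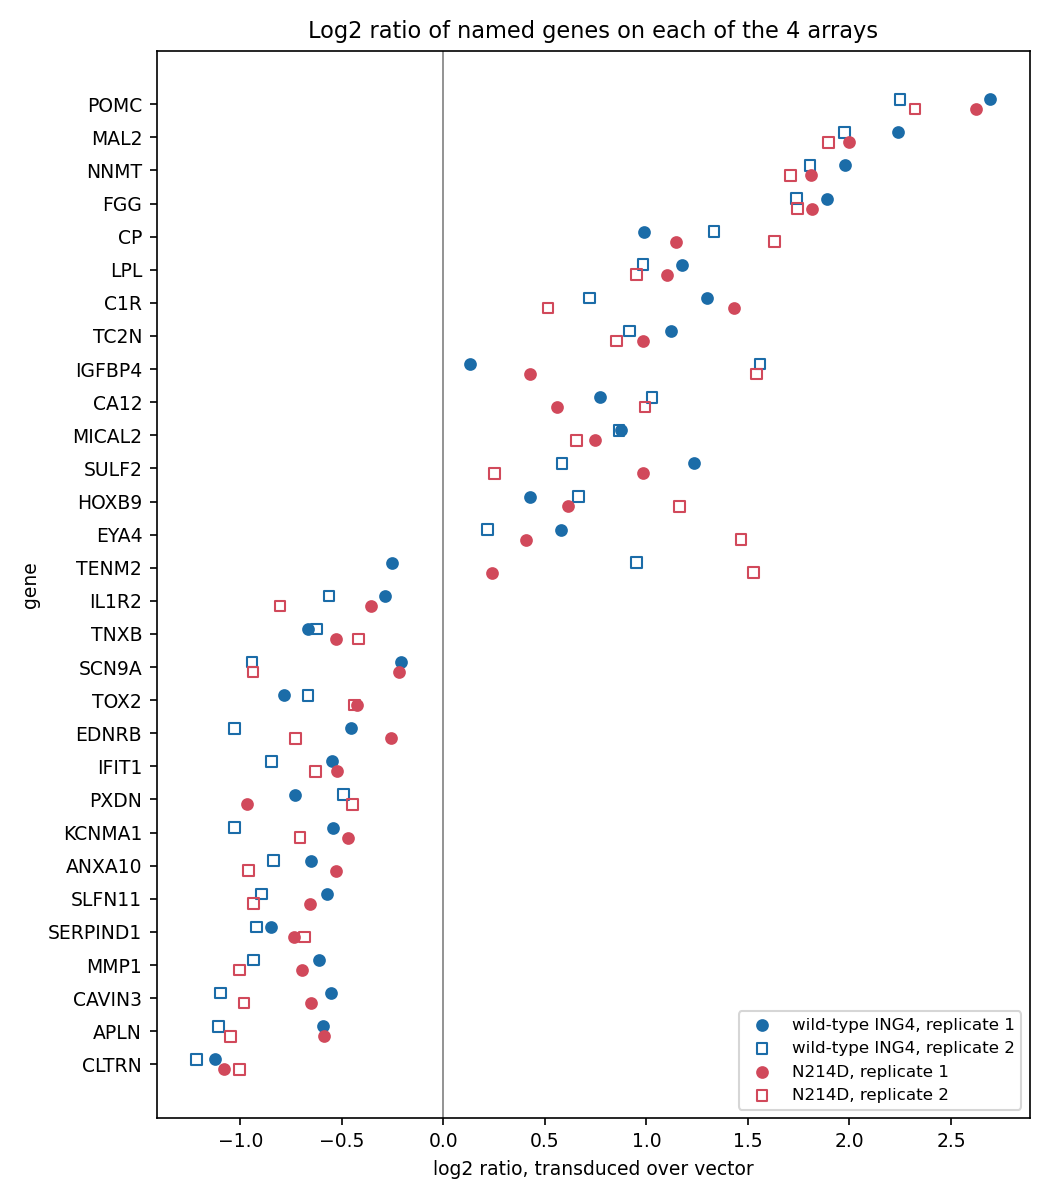
Log2 ratio of transduced over vector cells (horizontal axis) of genes named by the rule in either comparison against vector, with the spots of the streaked columns left out, on each of the 4 arrays. Circles are replicate 1 arrays and squares replicate 2 arrays, in blue for wild-type ING4 and red for N214D. POMC lay between 2.25 and 2.69 and CLTRN between -1.22 and -1.01.

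Of the 41 gene lists, 10 shifted between the cells labelled wild-type ING4 and vector cells in limma's camera with a preset correlation of 0.01. This test, like the list p-values below unless the block is named, was run without the replicate block. Members said to rise, fall or not pass are those of the fit with the block, as 0 genes passed without it. None held with an estimated correlation, which rests on 2 residual degrees of freedom and so can hardly pass a list here. The G2/M and mitosis genes shifted furthest, with a median of 0.32 (camera adjusted p = 2.43e-29, or adjusted p = 0.220 with an estimated correlation): of the 39 members measured, 26 rose, 0 fell and 13 did not pass (34 higher and 0 lower when adjusted over the list alone). NDC80, a kinetochore protein, rose by 0.57 ± 0.06, the cyclin CCNB2 by 0.51 ± 0.06 and the mitotic kinesins KIF2C and KIF23 by 0.50 ± 0.06 and 0.49 ± 0.06. The median of these genes was 0.28 and 0.25 on the single arrays. The list of genes of ATF4 and amino acid stress shifted up (median 0.16, camera adjusted p = 3.09e-09, or adjusted p = 0.295 with an estimated correlation), and of the 26 members measured, 9 rose, 0 fell and 17 did not pass (13 higher and 0 lower when adjusted over the list alone). NUPR1, a stress-induced regulator, rose by 0.40 ± 0.06 and the amino acid transporter SLC7A5 by 0.34 ± 0.06. STC2 (0.37 ± 0.06) and MTHFD2 (0.29 ± 0.06) also rose. NF-kappaB targets shifted up (median 0.16, camera adjusted p = 3.94e-07, or adjusted p = 0.295 with an estimated correlation), and of the 28 members measured, 10 rose, 0 fell and 18 did not pass (16 higher and 2 lower when adjusted over the list alone). The prostaglandin synthase PTGS2 rose by 0.77 ± 0.06, the chemokines CXCL2 and CXCL3 by 0.75 ± 0.06 and 0.63 ± 0.06, and NFKBIZ by 0.49 ± 0.06. Targets of p53 shifted up (median 0.12, camera adjusted p = 9.98e-06, or adjusted p = 0.295 with an estimated correlation), and of the 30 members measured, 9 rose, 1 fell and 20 did not pass (15 higher and 1 lower when adjusted over the list alone). GADD45A rose by 0.65 ± 0.06, the cytokine GDF15 by 0.44 ± 0.07, BTG2 by 0.44 ± 0.06 and PMAIP1 by 0.43 ± 0.06, although GDF15 was below 0 on 1 of its arrays.

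Further lists passed with a higher camera adjusted p at the preset correlation. MYC and nucleolar genes shifted up (median 0.12, camera adjusted p = 1.72e-04, or adjusted p = 0.414 with an estimated correlation), and of the 30 members measured, 6 rose, 0 fell and 24 did not pass (7 higher and 0 lower when adjusted over the list alone). DKC1 rose by 0.38 ± 0.06 and NOP58 by 0.36 ± 0.06. Interleukins and colony-stimulating factors shifted up (median 0.07, camera adjusted p = 0.00216, or adjusted p = 0.391 with an estimated correlation), and of the 16 members measured, 3 rose, 1 fell and 12 did not pass (5 higher and 1 lower when adjusted over the list alone). IL6 rose by 0.42 ± 0.06, IL1A by 0.31 ± 0.06 and IL18 by 0.29 ± 0.06, and TNFSF4 fell, at -0.21 ± 0.06. The median log2 intensity of the interleukin list was low, at 7.52 against 10.2 for the G2/M list. The IGF axis shifted up (median 0.03, camera adjusted p = 0.0485, or adjusted p = 0.414 with an estimated correlation), and of the 18 members measured, 5 rose, 1 fell and 12 did not pass (7 higher and 1 lower when adjusted over the list alone). Within it the binding protein IGFBP4 rose by 0.85 ± 0.07 and IGFBP7 fell, at -0.43 ± 0.06. IRS1 (0.40 ± 0.06) and STC2 rose. Oxidative phosphorylation shifted down (median -0.05, camera adjusted p = 0.0241, or adjusted p = 0.414 with an estimated correlation), but only NDUFB3 passed among its 46 members, at -0.24 ± 0.06, and 0 passed when adjusted over the list alone. This list had medians of 0.02 and -0.19 on the single arrays.

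Interferon-stimulated genes shifted down (median -0.13, camera adjusted p = 9.98e-06, or adjusted p = 0.295 with an estimated correlation), and of the 34 members measured, 0 rose, 8 fell and 26 did not pass (2 higher and 14 lower when adjusted over the list alone). IFIT1 stood at -0.70 ± 0.06, RIGI, a sensor of viral RNA, at -0.61 ± 0.06, IFI44 at -0.47 ± 0.06 and OAS1 at -0.42 ± 0.06. Matrix proteases and their inhibitors shifted down (median -0.06, camera adjusted p = 2.60e-04, or adjusted p = 0.295 with an estimated correlation), and of the 31 members measured, 1 rose, 9 fell and 21 did not pass (1 higher and 12 lower when adjusted over the list alone). Besides MMP1, the plasminogen activators PLAT and PLAU fell, at -0.51 ± 0.06 and -0.46 ± 0.06. TIMP3, an inhibitor of metalloproteinases, rose by 0.64 ± 0.06. Factors of the senescence-associated secretory phenotype (SASP) did not pass as a list (median 0.01, camera adjusted p = 0.438), and its members went both ways: of the 44 members measured, 8 rose, 7 fell and 29 did not pass (16 higher and 7 lower when adjusted over the list alone). IGFBP4, CXCL2 and CXCL3 rose and MMP1 fell. Among 9 chemokines 2 rose, CXCL2 and CXCL3, 0 fell and 4 passed upward when adjusted over the list alone (camera adjusted p = 0.0620). Markers of endothelial cells, epithelial cells and leukocytes did not pass, with camera adjusted p of 0.0742, 0.298 and 0.160.

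With an array left out, the tested group keeps 1 array with the effect of its dyes, and that array is assumed to vary like those of the other construct. Without wild-type ING4 replicate 2, the lists of ATF4 (adjusted p = 0.144), p53 (0.144), MYC (0.849) and oxidative phosphorylation (0.818) did not pass. Without replicate 1, interleukins (adjusted p = 0.495) and matrix proteases (0.0534) did not, and without either the IGF axis did not (adjusted p = 0.0546 and 0.754). The IGF axis also did not pass without background subtraction (adjusted p = 0.0728), on the processed signals (0.0725), with a smaller offset (0.0574), with scaled arrays (0.0540) or in the value table (0.0649), but with the block it passed for both constructs (adjusted p = 0.0232 for wild-type ING4 and 0.0470 for N214D). Oxidative phosphorylation did not pass with median centring (adjusted p = 0.348), on the processed signals (0.0969) or in the value table (0.185). At the preset correlation, the G2/M, NF-kappaB and interferon lists passed without any 1 array. With fry and the block no list passed, the lowest adjusted p being 0.0586. The vector cells are 1 RNA sample and the only control, so the test leaves out their own spread. Unchanged groups were simulated against 1 vector sample, drawn with the residual spread of the fit with the block. They gave 1170 to 2687 calls in 100 draws, 2289 on average, against 1811 observed. The 1811 are therefore not shown to exceed what an unchanged group gives. With the block and the software's processed signals 0 genes passed, and with a smaller normexp offset 477.

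With N214D, the transcripts furthest above vector were again POMC, MAL2, FGG, NNMT and SUCNR1, and CLTRN was furthest below. In the fit with the replicate block, 23 of 39 G2/M and mitosis genes rose, and 10 of 34 interferon-stimulated genes, 12 of 41 genes of E2F and S phase and 6 of 30 genes of cholesterol and lipid synthesis fell. None of these lists passed in camera with an estimated correlation (adjusted p = 0.350, 0.350, 0.396 and 0.350 without the block, and 0.668 each with it). POMC rose by 2.47 ± 0.06 (adjusted p = 2.79e-08; 2.62 and 2.32 on the single arrays), MAL2 by 1.95 ± 0.06, FGG by 1.78 ± 0.06, NNMT by 1.76 ± 0.06, SUCNR1 by 1.74 ± 0.08 and CP by 1.39 ± 0.06. The other 6 of the 12 largest rises, DKK3, ZAN, HMGCLL1, AKAP12, CISH and STAT4, were measured in array columns 73 to 81, which held a streak on the N214D replicate 2 array. Their values were 2.52, 2.61, 2.56, 2.27, 2.40 and 2.20 on that array and 0.76, 0.35, 0.10, 0.28, 0.12 and 0.32 on the other. AKAP12 was also high on the wild-type ING4 replicate 2 array, at 1.56, with -0.32 on wild-type ING4 replicate 1. SUCNR1, with 1.32 and 2.17, lay in these columns too. With these columns left out, a different probe of CISH gave -0.12. Applied without these columns, an alternative chosen after seeing the data, the rule also took LPL (1.03 ± 0.06), IGFBP4 (0.98 ± 0.07), C1R (0.97 ± 0.07), EYA4 (0.94 ± 0.17), TC2N (0.92 ± 0.06), HOXB9 (0.89 ± 0.07) and TENM2 (0.88 ± 0.06). EYA4 had 0.41 and 1.47 on the single arrays. In wild-type ING4 the same alternative added MICAL2 (0.87 ± 0.06) and IGFBP4 among the rises.

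**Figure D2:**
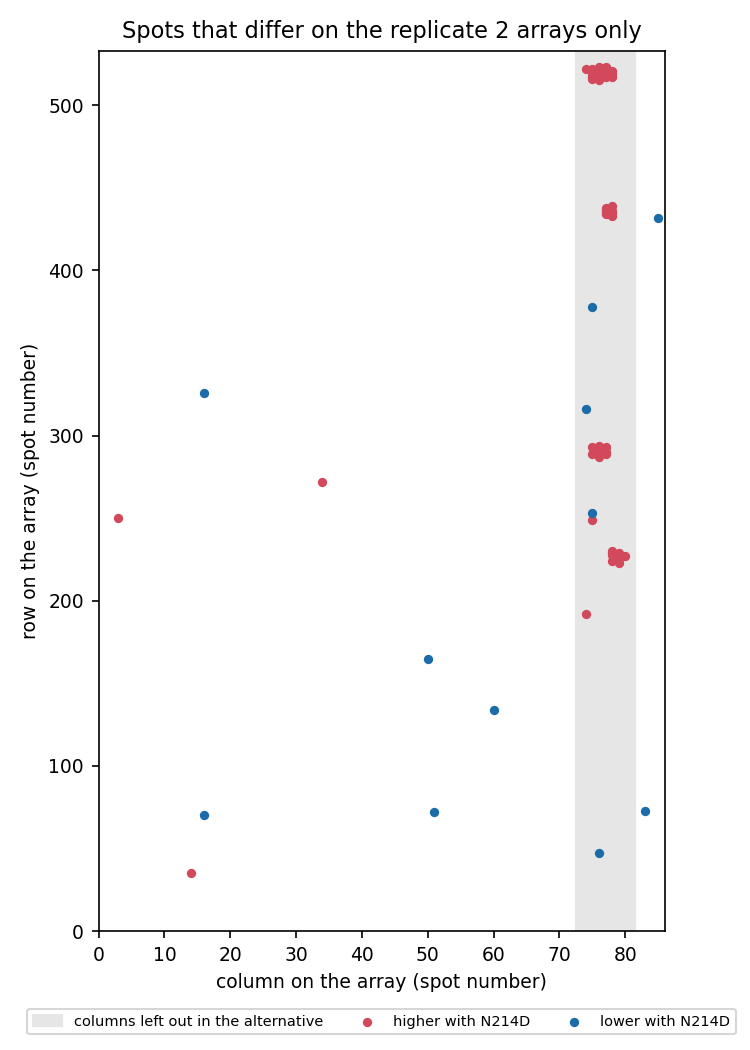
Position on the array, as column (horizontal) and row (vertical) number of the spot, of the 62 spots whose log2 ratios differed by over 1 between N214D and wild-type ING4 on the replicate 2 arrays and by under 0.5 on the replicate 1 arrays. Red spots were higher with N214D and blue ones lower, and 52 of them lay in the grey columns 73 to 81.

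CLTRN had the largest fall with N214D, at -1.04 ± 0.06 (adjusted p = 1.30e-05). LBX1 (-1.02 ± 0.21) lay in the streaked columns, with -0.25 and -1.79 on the single arrays, as did NGEF (-0.69 ± 0.06). MMP1 stood at -0.85 ± 0.06, APLN at -0.82 ± 0.06, CAVIN3 at -0.82 ± 0.06, SLFN11 at -0.80 ± 0.06 and ANXA10 at -0.75 ± 0.06. SERPIND1 stood at -0.71 ± 0.06, PXDN, a peroxidase of the matrix, at -0.71 ± 0.06, KCNMA1 at -0.59 ± 0.06 and the decoy receptor IL1R2 at -0.58 ± 0.06. Without the streaked columns SCN9A (-0.58 ± 0.06) and IFIT1 (-0.58 ± 0.06) followed. In the fit without the block, the smallest p belonged to FGG, NNMT, MAL2, POMC, SVEP1 and LPL above 0 and to CLTRN, SERPIND1, HS3ST1, ASTN2 (-0.58), MMP1 and B4GAT1 (-0.53) below 0. In limma 1692 genes were higher and 1268 lower with the block (1420 and 1490 with trended moderation), while 0 passed without it, with 467 at an unadjusted p under 0.05. None of the genes named from the fit without the block passed there, with adjusted p of 0.452 or more.

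With N214D, 14 of the 41 lists shifted under the preset correlation without the block, and none with an estimated correlation. Members said to rise or fall are again those of the fit with the block. The G2/M and mitosis genes again shifted up (median 0.25, camera adjusted p = 3.92e-16, or adjusted p = 0.350 with an estimated correlation), and of the 39 members measured, 23 rose, 0 fell and 16 did not pass (28 higher and 0 lower when adjusted over the list alone). KIF2C rose by 0.43 ± 0.06, the topoisomerase TOP2A by 0.43 ± 0.06, KIF23 by 0.41 ± 0.06 and the checkpoint kinase BUB1B by 0.40 ± 0.06. Genes of E2F and S phase went the other way (median -0.10, camera adjusted p = 2.01e-04, or adjusted p = 0.396 with an estimated correlation): of the 41 members measured, 2 rose, 12 fell and 27 did not pass (3 higher and 16 lower when adjusted over the list alone). The transcription factors E2F1 and E2F2 stood at -0.39 ± 0.06 and -0.37 ± 0.06, UHRF1 at -0.37 ± 0.06 and the ribonucleotide reductase subunit RRM2 at -0.36 ± 0.06. In wild-type ING4 the same list had a median of -0.08 and did not pass (camera adjusted p = 0.0620). The ATF4 list shifted up (median 0.18, camera adjusted p = 3.89e-13, or adjusted p = 0.350 with an estimated correlation), and of the 26 members measured, 12 rose, 0 fell and 14 did not pass (18 higher and 0 lower when adjusted over the list alone). SESN2 rose by 0.53 ± 0.06, PPP1R15A by 0.53 ± 0.06, STC2 by 0.48 ± 0.06 and SLC7A5 by 0.44 ± 0.06. NF-kappaB targets shifted up (median 0.11, camera adjusted p = 2.23e-04, or adjusted p = 0.350 with an estimated correlation), and of the 28 members measured, 10 rose, 0 fell and 18 did not pass (11 higher and 0 lower when adjusted over the list alone). PTGS2 rose by 0.73 ± 0.06, NFKBIZ by 0.51 ± 0.06, RELB by 0.38 ± 0.06 and CXCL2 by 0.36 ± 0.06.

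Targets of p53 (median 0.10, camera adjusted p = 0.00119, or adjusted p = 0.350 with an estimated correlation) shifted up with N214D, and of the 30 members measured, 8 rose, 1 fell and 21 did not pass (9 higher and 1 lower when adjusted over the list alone). GADD45A rose by 0.55 ± 0.06 and PMAIP1 by 0.49 ± 0.06. Interleukins and colony-stimulating factors (median 0.08, camera adjusted p = 0.00837, or adjusted p = 0.350 with an estimated correlation) shifted up, and of the 16 members measured, 3 rose, 0 fell and 13 did not pass (3 higher and 0 lower when adjusted over the list alone). Those that rose were IL1A (0.36 ± 0.06), IL18 (0.30 ± 0.06) and TSLP (0.26 ± 0.06), and the list did not pass with the replicate block (adjusted p = 0.0604). MYC and nucleolar genes (median 0.08, camera adjusted p = 0.0133, or adjusted p = 0.512 with an estimated correlation) shifted up, and of the 30 members measured, 6 rose, 0 fell and 24 did not pass (6 higher and 0 lower when adjusted over the list alone), with DKC1 among the rises (0.36 ± 0.06). Immediate early genes (median 0.09, camera adjusted p = 0.0232, or adjusted p = 0.519 with an estimated correlation) shifted up, and of the 29 members measured, 5 rose, 1 fell and 23 did not pass (9 higher and 3 lower when adjusted over the list alone). EGR1 rose by 0.50 ± 0.06 and JUN by 0.48 ± 0.06, the latter with -0.48 and 1.44 on the single arrays.

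Interferon-stimulated genes shifted down (median -0.10, camera adjusted p = 0.00119, or adjusted p = 0.350 with an estimated correlation), and of the 34 members measured, 1 rose, 10 fell and 23 did not pass (1 higher and 11 lower when adjusted over the list alone). IFIT1, IFI44 (-0.50 ± 0.06) and RIGI (-0.42 ± 0.06) fell. Cholesterol and lipid synthesis shifted down (median -0.11, camera adjusted p = 6.07e-05, or adjusted p = 0.350 with an estimated correlation), and of the 30 members measured, 0 rose, 6 fell and 24 did not pass (0 higher and 9 lower when adjusted over the list alone). LPIN1 stood at -0.28 ± 0.06, ACAT2 at -0.27 ± 0.06, EBP at -0.25 ± 0.06 and FADS1 at -0.23 ± 0.06. Matrix proteases and inhibitors shifted down (median -0.08, camera adjusted p = 0.00127, or adjusted p = 0.350 with an estimated correlation), and of the 31 members measured, 2 rose, 8 fell and 21 did not pass (2 higher and 10 lower when adjusted over the list alone). SERPINB2, an inhibitor of plasminogen activators, was at -0.50 ± 0.06 and ADAMTS6 at -0.39 ± 0.06, while TIMP3 rose by 0.79 ± 0.06. Oxidative phosphorylation (median -0.11, camera adjusted p = 0.00221, or adjusted p = 0.350 with an estimated correlation) shifted down, and of the 46 members measured, 0 rose, 7 fell and 39 did not pass (0 higher and 7 lower when adjusted over the list alone), with NDUFB3 at -0.31 ± 0.06. Heat shock genes (median -0.08, camera adjusted p = 0.0186, or adjusted p = 0.350 with an estimated correlation) shifted down, and of the 22 members measured, 1 rose, 4 fell and 17 did not pass (1 higher and 4 lower when adjusted over the list alone). HSPH1 fell, at -0.33 ± 0.06, and HSP90AB1 rose by 0.35 ± 0.06. Endothelial markers shifted down (median -0.10, camera adjusted p = 0.00779, or adjusted p = 0.350 with an estimated correlation), and of the 13 members measured, 0 rose, 2 fell and 11 did not pass (0 higher and 2 lower when adjusted over the list alone). SOX17 and KDR fell, at -0.24 ± 0.06 and -0.20 ± 0.06, and epithelial and leukocyte markers did not pass (camera adjusted p = 0.657 and 0.0674). The endothelial markers were dim, with a median log2 intensity of 6.86 against 10.2 for the G2/M list. SASP factors did not pass as a list (median 0.03, camera adjusted p = 0.568): of the 44 members measured, 10 rose, 8 fell and 26 did not pass (12 higher and 8 lower when adjusted over the list alone). IGFBP4 and AREG (0.52 ± 0.06) rose, and MMP1 and SERPINB2 fell. Among 9 chemokines, CXCL2 and CXCL3 (0.27 ± 0.06) rose, 0 fell and 2 passed upward when adjusted over the list alone (camera adjusted p = 0.354). With fry and the block the lists of G2/M, E2F, NF-kappaB and immediate early genes passed (adjusted p = 0.0461 each). With fry and no block none of them did (adjusted p = 0.327, 0.451, 0.346 and 0.898).

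With an N214D array left out, the 1 that stays is likewise assumed to vary like those of wild-type ING4. Without the N214D replicate 2 array 4 lists passed, not 14: the G2/M, ATF4 and heat shock lists were among those that passed, and the other lists described as shifted had adjusted p of 0.0658 (NF-kappaB) to 0.909 (MYC and immediate early genes, which turned direction). Without replicate 1, matrix proteases, endothelial markers, interleukins and heat shock genes did not pass, with adjusted p from 0.0919 (matrix proteases) to 0.874 (heat shock genes), and heat shock genes turned direction in the value table (adjusted p = 0.869). Heat shock genes also did not pass on the processed signals (adjusted p = 0.0809), with median centring (0.193) or with every probe (0.0695), interleukins on the processed signals (0.0552), with median centring (0.168) or without a filter on dim probes (0.0630), and oxidative phosphorylation with median centring (0.136). In the value table, where 1 N214D array is left, 6 lists passed. With the block, 0 genes passed on the software's processed signals and 1060 with a smaller normexp offset, and unchanged groups simulated against 1 vector sample gave 1287 to 2581 calls, against 2960 observed. The simulated vector varied only by the residual spread of the fit with the block. A vector culture may vary more, so the 2960 are not shown to exceed what an unchanged group gives.

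**Figure D3:**
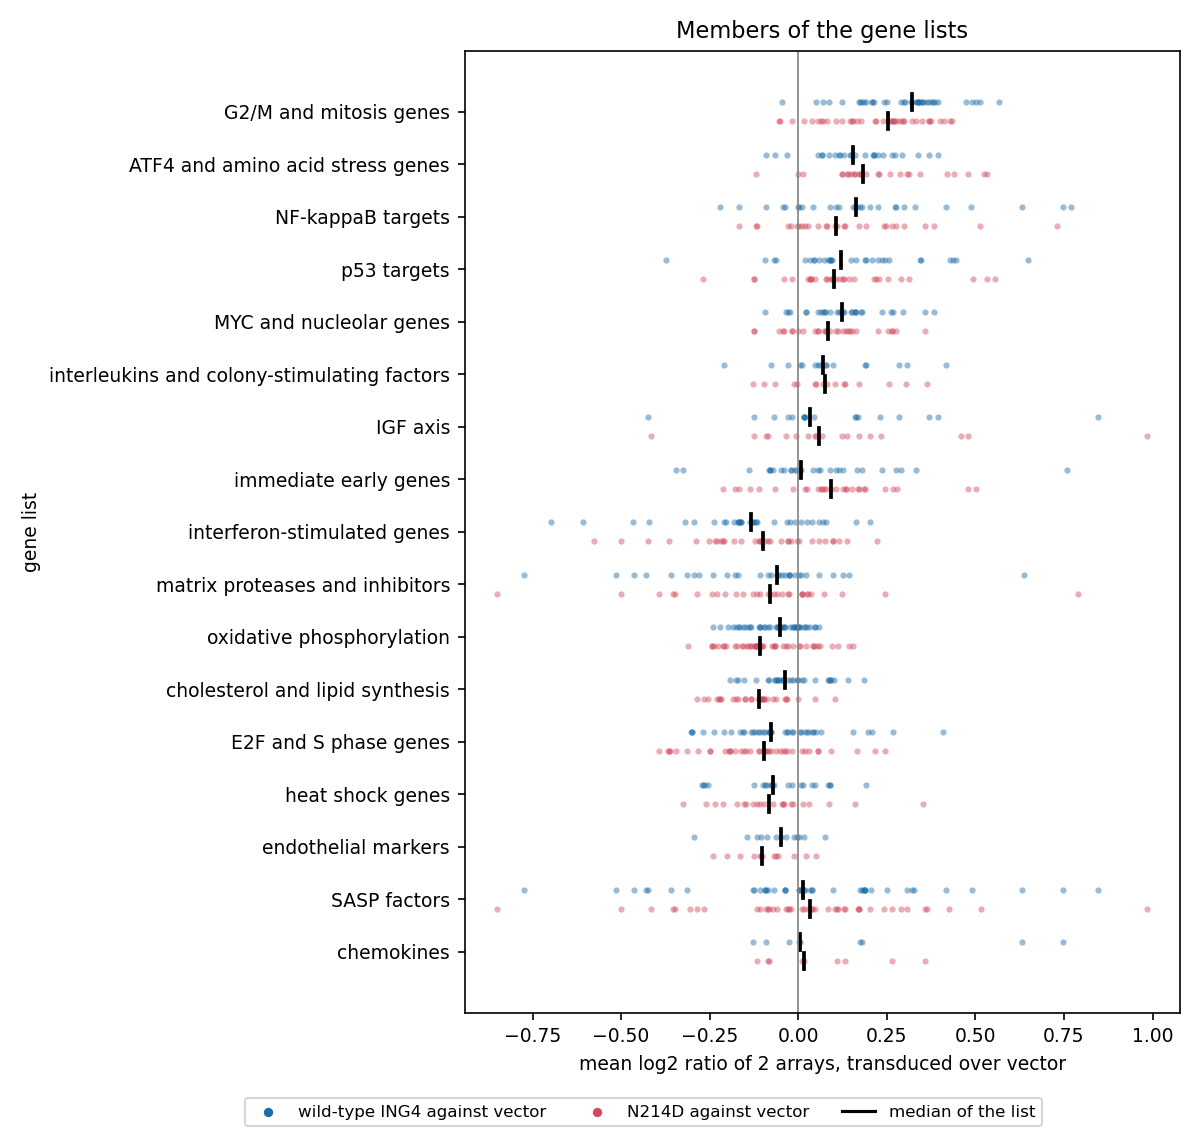
Mean log2 ratio over 2 arrays (horizontal axis) of each measured member of 17 gene lists, in blue for wild-type ING4 and red for N214D against vector. Black bars are medians. The median of the G2/M and mitosis genes was 0.32 and 0.25, and that of the interferon-stimulated genes -0.13 and -0.10.

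Set directly against wild-type ING4, where the vector sample cancels, few genes differed with N214D. Without the block 0 genes passed and 9 had an unadjusted p under 0.05 in limma, and with it 10 were higher and 1 lower with N214D. Within each replicate number, where both arrays have one dye orientation, 11 of these 11 differed the same way in both pairs. The fit with the block calls genes whose 2 pair differences lie close together, so this adds no support. Across orientations, ZCCHC2 was the 1 gene with a symbol whose N214D arrays both lay above both wild-type arrays (0.61 ± 0.08, adjusted p = 0.0498), and with arrays scaled to one spread 0 genes passed. By smallest p without the block, PATL1 (0.63 ± 0.09), OASL (0.31), GTF3C3 (0.30), IL4R (0.32), TOX2 (0.29) and TCIM (0.32) were on the higher side with N214D. On the lower side were, among others, SF3A3 (-0.41), CXCL3 (-0.37), GJB7 (-0.39), SLC26A1 (-0.32) and LIPG (-0.33). None of these genes passed in either fit. CXCL3 had 0.64 and 0.63 on the wild-type arrays and 0.23 and 0.31 on the N214D arrays. Cholesterol and lipid synthesis was lower with N214D as a list (median difference -0.10, camera adjusted p = 1.59e-04, or adjusted p = 0.866 with an estimated correlation), with LPIN1 at -0.37. The G2/M and mitosis genes (-0.07, camera adjusted p = 7.56e-04, or adjusted p = 0.866 with an estimated correlation) were lower too, with HMMR (-0.29) and CDK1 (-0.20) furthest below. So were genes of E2F and S phase (-0.07, camera adjusted p = 0.0468, or adjusted p = 0.910 with an estimated correlation), with TYMS (-0.31) and CDC45 (-0.27). No member of these lists passed, and 2 of 30, 0 of 39 and 0 of 41 were lower when adjusted over the list alone. With the replicate block the contractile genes were a further list, higher with N214D (median 0.08, adjusted p = 0.00659, or adjusted p = 0.859 with an estimated correlation): of the 14 members measured, 0 rose, 0 fell and 14 did not pass (4 higher and 0 lower when adjusted over the list alone). Of the lists that passed against vector for N214D and not for wild-type ING4 in both fits, cholesterol synthesis and E2F thus passed in this direct test as well, while heat shock genes (adjusted p = 0.705), immediate early genes (0.894) and endothelial markers (0.629), did not, nor did the IGF axis (adjusted p = 0.924). With 1 array left in a group, under the same assumption, leaving out wild-type ING4 replicate 1 ended the calls of all 3 lists that were lower with N214D (adjusted p = 0.241 for cholesterol synthesis, 0.241 for G2/M and 0.810 for E2F), as did leaving out wild-type ING4 replicate 2 (0.128, 0.159 and 0.128) or N214D replicate 2 (0.512, 0.280 and 0.919). The E2F list also did not pass on the processed signals (adjusted p = 0.172), with a smaller offset (0.109), with median centring (0.134), without a filter (0.0981) or without the streaked columns (0.0662), and cholesterol synthesis not with median centring (0.0654). In the value table none of the 3 passed, with adjusted p from 0.373 (cholesterol synthesis) to 0.555 (G2/M). Without N214D replicate 1, cholesterol synthesis alone of the 3 passed, with adjusted p of 0.230 for G2/M and 0.164 for E2F.

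Many of the same genes were called against vector for both constructs. With the replicate block 539 genes were higher and 537 lower in both comparisons against vector, POMC, NNMT, FGG and CLTRN among them, and 6 went opposite ways. Independent lists of these lengths would share 64.4 and 50.2, and unchanged groups simulated against 1 shared vector sample shared 190 to 540 higher and 184 to 527 lower calls in 100 draws. Across 23314 genes, which are not independent replicates, the log2 ratios of both constructs correlated with r = 0.644. The simulated r was 0.666 on average (0.655 to 0.677 in 100 draws), and the observed r lay below every draw. The simulated r was set by giving the vector the same spread as every other sample. Its place beside the observed r therefore says nothing about the constructs. The covariance of the log2 ratios was 0.0135, above every draw (0.00722 on average, 0.00701 to 0.00748). It differed from the simulated average by 0.00624. These ranges depend on the spread given to the vector sample. The vector sample could not be split, so its share in the overlap is not known. The test without the block shared 0 calls.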

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

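The tests of the dye effect and of scaled arrays here were chosen after the result was seen, while the fit with the replicate block was planned. With the replicate block, 11 genes differed between N214D and wild-type ING4, by a test of the difference itself, 10 of them higher with N214D. Named after their values were seen, they were AKAP12, TBL1XR1, ZNF365, UACA, ZCCHC2, OSBPL8, ZNF644, CSPP1, ACBD5 and 2 transcripts without a symbol, and AKAP12 lay in the streaked columns 73 to 81. TBL1XR1 differed by 0.81 and ZNF365 by 0.81 on the log2 scale. Within both replicate pairs, each of one dye orientation, 11 of the 11 differed the same way, and across orientations 2 had both N214D arrays on one side of both wild-type arrays. The former adds no support, since the fit with the block calls genes whose 2 pair differences lie close together. One candidate explanation is that the dye effect was not of one size on every array. The absolute dye effect of the 11 had a median percentile of 99.5 among all genes, which goes with it. The dye effect was below 0 in 11 of the 11. With the streaked columns included, the SD of log2 ratios was 0.231 (N214D) and 0.261 (wild-type ING4) on replicate 1, and 0.343 and 0.289 on replicate 2. Dye effects unequal in that way would raise N214D in both pairs. Against an unequal dye effect stands the transcript lower with N214D, at percentile 41.3, whose difference was -0.58 before and -0.59 after the arrays were scaled to one spread. After scaling 0 passed, but the median absolute difference of the 11 only went from 0.61 to 0.58 with SE of 0.08 to 0.10 before and 0.08 to 0.12 after, and the lowest adjusted p became 0.169. The absolute difference was smaller in 10 and larger in 1, and before scaling the adjusted p were 0.0274 to 0.0498, near the threshold, so the end of the calls does not decide between the dyes and a difference of the constructs, which stays open and untested.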

How the results depend on the processing

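The alternatives that read the dyes of replicate 2 as not exchanged, scale the arrays, leave out the streaked columns, need every array on one side or join the replicate block with another choice were added after seeing the data. In the order wild-type ING4 against vector, N214D against vector and N214D against wild-type ING4, the counts of 0 became 1811, 2960 and 11 with the replicate block, whose paired arrays share a dye orientation, and the calls shared by both constructs 1076. In the simulated data a dye effect left in the error hid 2-fold changes. That followed from how those data were made, so it does not settle why the counts rose on the real arrays. The value table, with 3 arrays, gave 19, 1 and 0, and dyes of replicate 2 read as not exchanged gave 130, 199 and 0. Every other alternative without the block kept 0 in limma, with 0 to 782 genes at an unadjusted p under 0.05. With each array left out in turn, which leaves its group 1 array assumed to vary like those of the other construct, there were 0 calls throughout. With the block this leaves no residual degree of freedom, so no test.

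With the block and a further choice, the same 3 counts were 0, 0 and 0 on the processed signals, 477, 1060 and 0 with an offset of 16, 889, 1342 and 88 with median centring, and 5953, 5884 and 0 with dyes not exchanged. Calls with every array on one side numbered 1397, 1924 and 2. The difference between the constructs held 1 call without background subtraction, 1 with the strict filter, 1 with trended moderation, 59 without a filter, 62 over probes, 0 with scaled arrays and 17 without the streaked columns. The counts against vector stayed within 1.5 times of 1811 and 2960 there. Trended moderation moved the split to 635 higher and 1101 lower for wild-type ING4 and to 1420 higher and 1490 lower for N214D, where it turned the balance. The cause of these changes was not tested.

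The numbers of shifted lists, 10, 14 and 3, became 22 for wild-type ING4 with every probe, 6 for N214D in the value table, and for the difference 6 without background subtraction, 5 with the strict filter, 8 with every probe and 1 in the value table. Leaving out arrays gave 8 to 12, 4 to 15 and 1 to 2 lists. With the dyes of replicate 2 read as not exchanged, 1, 1 and 0 lists passed. At the preset correlation, the G2/M list passed upward for both constructs against vector in each of the 17 other alternatives run without a second choice, but not with an estimated correlation. The correlation of the constructs was 0.359 in the value table and 0.0279 to 0.576 with an array left out, lowest without wild-type ING4 replicate 2. With any array left out the dyes no longer cancel in its group, and why this array gave the lowest value was not tested. ING4 passed nowhere, and without single arrays its log2 ratio ran from -0.21 to 0.11, from -0.16 to 0.00747 and, for the difference, from -0.19 to 0.13. Of 190 values of named genes past the threshold with the block, 58 no longer passed with an offset of 16 and all 190 on the processed signals. Without the streaked columns, where another probe stands in, AATK turned to 0.0331 for wild-type ING4. CISH with N214D turned to -0.124 there and with the strict filter, and to -0.338 on the processed signals. Signal over background limits which probes count: 29797 of 41000 passed the filter.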

Other observations

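Complement and coagulation factors moved both ways in the fit with the replicate block. For wild-type ING4, of the 21 members measured, 5 rose, 6 fell and 10 did not pass (5 higher and 10 lower when adjusted over the list alone). The complement component C3 rose by 0.55 ± 0.06 and coagulation factor F10 by 0.46 ± 0.06, beside C1R and against the fall of SERPIND1. For N214D, of the 21 members measured, 5 rose, 6 fell and 10 did not pass (6 higher and 6 lower when adjusted over the list alone), with C3 at 0.47 ± 0.06 and F10 at 0.49 ± 0.06. Among markers of senescence and inhibitors of cyclin-dependent kinases, of the 22 members measured, 2 rose, 4 fell and 16 did not pass (3 higher and 4 lower when adjusted over the list alone) for wild-type ING4. HMGB2, a chromatin protein of cycling cells, rose by 0.57 ± 0.06, and the inhibitors CDKN2D, CDKN2C and CDKN1C fell, at -0.53 ± 0.06, -0.44 ± 0.06 and -0.35 ± 0.06. With N214D, of the 22 members measured, 6 rose, 4 fell and 12 did not pass (7 higher and 5 lower when adjusted over the list alone). There HMGB2 rose by 0.36 ± 0.06, while CDKN2C (-0.48 ± 0.06) and CDKN2D (-0.42 ± 0.06) fell. Neither list shifted as a whole in the fit without the block, with camera adjusted p of 0.132 and 0.359 for wild-type ING4 and 0.934 and 0.781 for N214D.

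Of growth factors and their receptors, of the 32 members measured, 5 rose, 1 fell and 26 did not pass (7 higher and 2 lower when adjusted over the list alone) for wild-type ING4. FGF9 rose by 0.52 ± 0.06, the EGF receptor ligand AREG by 0.49 ± 0.06 and PDGFRB by 0.33 ± 0.06. With N214D, of the 32 members measured, 5 rose, 4 fell and 23 did not pass (8 higher and 4 lower when adjusted over the list alone). There AREG and FGF9 (0.46 ± 0.06) rose and FGF7 fell, at -0.30 ± 0.06 (camera adjusted p = 0.0620 and 0.0549). The list of the HBO1 complex, the ING family and regulators of H3K4 passed for wild-type ING4 in the fit with the block (adjusted p = 0.0327, or adjusted p = 0.633 with an estimated correlation), and of the 27 members measured, 2 rose, 0 fell and 25 did not pass (2 higher and 0 lower when adjusted over the list alone), with ING5 at 0.30 ± 0.06 and CREBBP at 0.23 ± 0.06 past the threshold. For N214D it did not (adjusted p = 0.0635; 0.798 for the difference between the constructs), although EP300 (0.32 ± 0.06), BRPF1 (0.23 ± 0.06) and ING2 (-0.26 ± 0.06) passed as single genes.

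The tests on the dyes below were chosen after the result was seen, as were those of a difference between the constructs in the streak, and the test of a local defect before. On arrays labelled as exchanged, red-over-green ratios correlated above 0 across genes (r = 0.52 for wild-type ING4 and 0.47 for N214D), where a response to the constructs would turn them. Ribosomal proteins show it as a list, with medians of -0.59 and 0.70 for wild-type ING4 and -0.62 and 0.67 for N214D, and 0.05 and 0.02 as group means. They were bright, with a median log2 intensity of 15.8, and red signals were saturated at 546 to 662 spots per array against 0 green. Saturation of the red channel is therefore not told apart from a dye effect in this list. Against unexchanged dyes, the red-over-green difference of the constructs correlated at -0.107 between replicates 1 and 2 (bootstrap interval -0.124 to -0.0924) once its trend on the dye effect was removed, below 0 as exchanged dyes require. The bootstrap resampled genes, which are not independent replicates, so its interval does not measure the spread between arrays. A gene-specific dye effect is consistent with the correlation of 0.908 between the deviations of the 2 constructs. Because 100% of the replicate numbers hold one dye orientation, an infection batch that follows the number cannot be told apart from the dyes.

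A streak on one array is a further pattern: between the replicate 2 arrays 62 spots differed by over 1 (log2) and by under 0.5 between the replicate 1 arrays, against 2 spots the other way round. Of all spots that differed by over 1 between the replicate 2 arrays, 53 lay in columns 73 to 81, with a median difference of 2.15, and their median difference the same way on the replicate 1 arrays was 0.0333 (bootstrap interval -0.01 to 0.09), which argues against a difference of that size between the constructs. The 11 spots in other columns had 1.25 and 0.19 (0.02 to 0.22), and a smaller difference stays open there, as 9 of them went the same way. Both intervals come from resampled spots of the same arrays, so they do not measure the spread between arrays. A local defect on the array surface is consistent with the median distance of 1 spot step from each of the 62 to the nearest of them, below the 8.60 that was the lowest of 1000 random sets of spots. In all, 30 of the 38 genes called over 2-fold higher with N214D were measured in columns 73 to 81, which hold 10.6% of the spots.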
